A study of Arabidopsis thaliana with 8 samples.

How the data were processed

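RNA from control and systemic leaves of wild-type and dTLec plants was hybridised by the submitters to Affymetrix ATH1 arrays, 1 array per sample and 2 per group, from 10 µg of total RNA, per the labels' protocols. The plants grew for 5 weeks in 10 h of light and 14 h of darkness at 21 °C, after 2 days in the dark at 4 °C. The labels do not say whether the control leaves came from separate unwounded plants.

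The deposited values are log2 expression values per probe set, normalized between arrays by the authors. The tools named are RMA and Partek, per the submitters' processing notes, and their versions, settings and roles are not given in the sources used here. That the scale is log2 was read from the deposited values themselves, which run from 3.24 to 14.28 with almost equal means and medians on every array. Normalization that gives all arrays nearly the same distribution removes any shift shared by all transcripts, so each difference is relative to the typical probe set. Arrays have no read depth. The number of arrays limits the precision, and differences between probe sets near the lower end of the range are compressed.

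Of 22810 probe sets, 64 array controls were left out and 22746 were tested. Genes were named through the platform annotation of the array, updated by gene identifier with the TAIR10.1 gene table. Of the tested probe sets, 13513 had 1 gene, 503 had several and 8730 had none, and only those with 1 gene are named. The identifiers of 13436 probe sets were found in the gene table, as 13286 loci. No genome build is named for the array values, so no coordinates are given. The chip carries probes for a gene's 3′ end, and related genes can share them.

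Samples were grouped by genotype and leaf type from their titles. A linear model with 1 mean per group was fitted to all 8 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, and 7 comparisons were taken from it: systemic against control leaves in each genotype, the difference of these responses, dTLec against wild type in each leaf type, and the mean effects of leaf type and genotype. The model leaves 4 residual degrees of freedom, to which the prior added 3.124. At the named genes checked, the replicate 1 and replicate 2 arrays had equal means over the 4 groups. The difference between replicate numbers was thus already removed from the deposited values, which uses up part of the 4. The main p-values are therefore too small and the main counts too high. A fit with the replicate number as a block takes this into account, and its counts are given beside them. Tests were two-sided with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. The model, the alternatives, the gene lists and the rule for named genes were set before the data were examined.

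Per comparison of 2 groups, the rule named the 8 highest and 8 lowest log2 fold changes among probe sets past the threshold that match 1 gene and whose groups do not overlap. Where fewer than 5 probe sets passed, as for the difference of the responses and for control leaves, it took the 5 smallest p, as values. It also took the leading members of lists that passed, and 10 jasmonate, salicylate and stress genes in any case, of which PDF1.2 was measured by name. The examples from the mean effects were taken from the same rule's genes, and the other list members are named to give every list's result. Giving 2 unnamed probe sets also for systemic leaves was decided after their values were seen. Probe sets without a gene name are described by their values.

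The 24 fixed lists held 286 genes, and 36 of them had a named probe set. A gene with several probe sets was counted by the brightest. The 6 lists with at least 3 measured members were tested with limma's camera (preset correlation 0.01, and an estimated correlation beside it) and fry, adjusted over the 6 lists. No list that passed in camera with the preset correlation passed with the estimated one. The lists of JAZ repressors, ethylene, heat shock, xylem and epidermis had 0 members measured by name. Whether probe sets without a gene name in the annotation used measure them was not checked. After the annotation was seen to name few list members, 46 gene families taken from shared symbol beginnings, and the plastid-encoded genes among them, were added with at least 5 measured members each.

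The slope of the dTLec on the wild-type response was taken through 0 with the mean response as the weight, over probe sets past the threshold on that mean. It was added after the data were examined, and its test was set before its value was seen. Simulated arrays with means and spreads estimated from the real arrays and 200 changed probe sets were used to test the model. At a log2 change of 1 it recovered 94.0% of the changed probe sets for the wild-type response, 94.0% for the dTLec response, 73.1% for the difference of responses, 95.5% for control leaves, 91.0% for systemic leaves and 100% for both mean effects. Beside the 200 changed probe sets there were 4 to 9 false calls per comparison, and 21 for the mean effect of genotype. At a log2 change of 0.5 the difference of responses was recovered in 0% of cases. Simulated slopes of 1 and 0.6 were found as 0.997 and 0.601. camera called 2 of 50 unchanged and 50 of 50 shifted sets of 4 genes. The simulated probe sets varied independently of each other. The camera result therefore does not cover lists of correlated genes, such as jasmonate turnover, with an estimated correlation of 0.63. Nor do the simulated slopes show the precision of the real one, because deviations that many probe sets of an array share were not simulated. With single arrays left out the real slope ran from 0.503 to 0.758. The recovered shares and the false calls likewise describe the simulated arrays and may differ in the real ones.

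Alternatives covered centring each array, cyclic loess, a filter on dim probe sets, leaving out probe sets that can match several genes, a trended robust prior, no moderation, only the groups compared, the replicate number as a block, a 2-fold threshold, and leaving out each array. In that last setting a group keeps 1 array, which is assumed to vary like the other groups. Figures were drawn with matplotlib 3.10.9 and the permutation tests run with numpy 2.4.6 in Python 3.11.15.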

Results

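Transcript levels were measured in rosette leaves of 5-week-old Arabidopsis thaliana plants of 2 genotypes, the wild type (ecotype Col-0) and the SALK insertion line dTLec1-1, called dTLec here. Some of the rosette leaves were crushed across the midvein with tweezers, and RNA was taken 2 h later from control leaves and from systemic leaves, the usual term for unwounded leaves of a wounded plant. Each of the 4 groups had 2 arrays, and each of the 8 arrays gave log2 expression values for 22810 probe sets. The array medians lay between 5.82 and 5.87. Across probe sets, which are not independent replicates, the replicate arrays of a group correlated with r between 0.992 and 0.996. Some control arrays of different genotypes were more alike than the wild-type control replicates (r 0.9919). Between wild-type control replicate 2 and dTLec control replicate 1, r was 0.9955, and between wild-type control replicate 1 and dTLec control replicate 2 it was 0.9933. Both pairs carry different replicate numbers. Such pairs look more alike once the difference between replicate numbers is removed, so these values do not show that the genotypes are closer than replicates. With 2 arrays per group, the precision of every difference is limited. The labels do not say whether the replicates came from separate plants or pools, so the p-values measure only the spread between these samples, which may be technical. The labels name no gene for the insertion, and its transcript was therefore not checked.

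The first comparison asked how systemic leaves of wild-type plants differed from control leaves. Among the genes named here, LTI30, a dehydrin of cold and drought responses, rose 20.4-fold, with a log2 fold change of 4.35 ± 0.29 (SE, n = 2 arrays per group). AT2G38240 (JOX4) and JRG21 (AT3G55970, JOX3), which encode dioxygenases that oxidise jasmonic acid, rose 27.2-fold and 17.7-fold. AT1G10585, which encodes a bHLH protein, rose 19.6-fold, by 4.29 ± 0.27 on the log2 scale. The largest increase among the named genes was 36.1-fold, in AT1G15010. AT1G51090, encoding a protein with a heavy-metal-associated domain, AT4G30650 and the hydrolase gene AT5G06570 rose 23.8-fold, 13.1-fold and 12.9-fold. The decreases of named genes were smaller. EXPA8, encoding an expansin, had a log2 fold change of −1.76 ± 0.33, XTH33, encoding a xyloglucan endotransglucosylase/hydrolase, of −1.64 ± 0.27, and AT3G07010, encoding a pectate lyase, of −1.59 ± 0.19 (SE, n = 2 arrays per group). AT5G28630 (−1.90), AT3G13672 (SINA2, −1.72), AT1G67910 (−1.68), the receptor kinase gene AT5G59680 (−1.62) and IQD28 (−1.61) were the others of the 8 largest decreases among named genes. The adjusted p of the 8 raised genes lay between 0.000845 and 0.00505, and that of the 8 lowered genes between 0.00231 and 0.0157, in limma's moderated test with Benjamini-Hochberg adjustment.

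In all, 2716 of 22746 probe sets passed an adjusted p of 0.05 in the wild type (limma), 1344 higher and 1372 lower in systemic leaves. With the replicate block 1596 passed, 891 higher and 705 lower. Which direction had more calls depended on the processing, with 1418 higher and 1170 lower after centring each array, 1563 and 1053 after cyclic loess, and more higher than lower with any single array left out. Changes of at least 2-fold were mostly increases, 488 against 131 decreases. Both systemic arrays lay above or below both control arrays at 51.9% of all probe sets, against 33.3% by chance. This held for each of the 2716, which passing with 2 arrays per group nearly requires. The count was 806 without wild-type systemic replicate 2, 1341 without wild-type systemic replicate 1 and 1665 without wild-type control replicate 2. All 16 genes named above kept their direction when any single array was left out, and 13 of them still passed without wild-type systemic replicate 2, where the largest adjusted p was 0.0866.

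Of the 6 gene lists tested, all fixed before the data were examined, jasmonate turnover was the one that passed in the wild type. Of its 10 genes, 4 were measured by name, all of them JOX dioxygenase genes, so its results speak for these 4 and not for jasmonate turnover as a whole. All 4 rose, and all 4 also passed when adjusted over the list alone. The log2 fold changes were 4.76 for JOX4, 4.15 for JRG21 (JOX3), 3.44 for JOX2 (AT5G05600) and 0.55 for JOX1 (AT3G11180), with a median of 3.79. Their shift against all other genes had an adjusted p of 6.13e-06 in limma's camera test with a preset correlation between genes, and the adjusted p was 0.259 with an estimated correlation. JOX1 no longer passed without wild-type systemic replicate 1 (adjusted p 0.15), wild-type control replicate 2 (0.109) or wild-type systemic replicate 2 (0.0587, limma).

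Some single members of lists too small to test, and 1 of 3 auxin genes, also passed in the wild type. The cold-response genes COR15A and COR15B rose by 3.07 ± 0.44 and 1.58 ± 0.14 (log2 fold change ± SE, n = 2 arrays per group), and COR47, a dehydrin gene, by 2.25 ± 0.35, with adjusted p between 0.00162 and 0.00836 (limma). OPCL1, an enzyme of jasmonate biosynthesis, rose by 0.88 ± 0.16 (limma adjusted p 0.0149). UGT74B1, a glucosinolate glucosyltransferase, rose by 0.83, AT2G04400, an indole-3-glycerol phosphate synthase of tryptophan synthesis, by 1.17, and BCAT4, an enzyme of methionine-derived glucosinolate synthesis, by 1.14. GH3.3, an auxin-conjugating enzyme and the member of the auxin list that passed over all probe sets, rose by 1.33. Without wild-type systemic replicate 2 the limma adjusted p was 0.055 for COR47, 0.059 for GH3.3, 0.0607 for AT2G04400, 0.0651 for UGT74B1, 0.0887 for OPCL1 and 0.0961 for BCAT4.

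The remaining fixed lists also had few members measured by name, so their wild-type values speak for those members and not for the whole lists. No member passed over all probe sets among the 3 measured members each of the lists of jasmonate-responsive defence, rapid stress transcription factors, touch and calcium binding, and anthocyanin synthesis. With the auxin list, their camera adjusted p lay between 0.231 and 0.864. PDF1.2, a defensin gene that jasmonate and ethylene induce, had a log2 fold change of 0.39 ± 0.46 in the wild type and −0.11 ± 0.46 in dTLec (SE, n = 2 arrays per group), neither past the threshold. Adjusted over the list alone, CML37 (0.36) passed in the touch list, WRKY53 (−0.72) in the stress list and IAA29 (−0.42) in the auxin list beside GH3.3. WRKY53 had an adjusted p of 0.0538 over all probe sets, which was 0.022 without either dTLec control array and 0.0462 without either dTLec systemic array (limma). The camera adjusted p of the touch list was 0.0492 without wild-type systemic replicate 1. Measured members of the salicylate (GRX480, 0.42), oxidative stress (AT2G21640, −0.13, and GSTU25, −0.09), photosynthesis (LHCB4.2, −0.17, and RCA, 0.04), clock (GI, 0.21) and sugar-response (APL3, −0.44) lists did not pass. APL3 had a log2 fold change of −0.66 with an adjusted p of 0.0435 without wild-type systemic replicate 1 (limma).

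The same question was asked in dTLec. Among named genes, LTI30 rose 13.3-fold, by 3.73 ± 0.29 on the log2 scale (SE, n = 2 arrays per group). AT5G47330, a hydrolase gene, rose 9.85-fold, AT1G51090 7.93-fold, AT3G51450, a strictosidine synthase-like gene, 7.34-fold, and AT5G55050, a GDSL lipase gene, 6.85-fold. AT3G47380, encoding a pectin methylesterase inhibitor-like protein, AT1G14780 and the glycosyl hydrolase gene AT5G55180 rose by 2.63, 2.61 and 2.59 on the log2 scale. AT4G10910 fell 2-fold. The others of the 8 largest decreases among named genes had log2 fold changes of −1.33 for AT5G28630, −0.85 for the copper amine oxidase gene AT3G43670, −0.84 for AT5G49100, −0.81 for AT5G57785, −0.70 for AT1G70740, and −0.67 for both AT4G36550 and AT5G61590, the wax synthesis repressor DEWAX. The adjusted p of these 16 genes lay between 0.0209 and 0.0491 (limma).

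The number of probe sets past the threshold in dTLec was 152 (limma), 111 higher and 41 lower, and 70 of them changed at least 2-fold. At an unadjusted p under 0.05 the number was 3747. With the replicate block 16 passed the adjusted threshold, 15 higher and 1 lower. Both systemic arrays lay outside the range of the control arrays at 47.1% of all probe sets. This held for all 152, which passing with 2 arrays per group nearly requires. The count was 0 without dTLec control replicate 1, dTLec control replicate 2, dTLec systemic replicate 2, wild-type systemic replicate 1 or wild-type systemic replicate 2, and 390 without either wild-type control array. The wild-type arrays enter this comparison through the shared estimate of the spread and leave its fold changes as they are. Without dTLec systemic replicate 1 the count was 128, and 8 of the 16 named genes passed.

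No jasmonate turnover gene measured by name passed over all probe sets in dTLec, while 3 of the 4 passed when adjusted over the list alone. The log2 fold changes were 2.52 for JOX2 (AT5G05600), 1.77 for JRG21 (JOX3) and 0.08 for JOX1, with adjusted p of 0.0553, 0.108 and 0.777 (limma). JOX4 (AT2G38240) went from a mean of 7.08 ± 0.30 (SD, n = 2) in control leaves to 10.38 ± 0.77 in systemic leaves (adjusted p 0.0574), and the median log2 fold change of the 4 was 2.14. The camera adjusted p of the list was 0.000502, and the adjusted p was 0.235 with an estimated correlation. COR15A and COR47 had log2 fold changes of 2.53 ± 0.44 and 1.99 ± 0.35 (SE, n = 2 arrays per group), both with an adjusted p of 0.0642, and COR15B had 0.63 ± 0.14 with 0.104. Without either wild-type control array the adjusted p was 0.00677 for AT2G38240, 0.0193 for AT5G05600, 0.0329 for JRG21, 0.00742 for COR15A, 0.0108 for COR47 and 0.0468 for COR15B (limma). Without dTLec systemic replicate 1 the log2 fold change of AT5G05600 was 3.07, with an adjusted p of 0.0303. The auxin list had a median of 0.59 and a camera adjusted p of 0.0218, and the adjusted p was 0.235 with an estimated correlation. In it GH3.3 (1.18, adjusted p 0.0625) passed over the list alone, and over all probe sets without either wild-type control array (0.0316, limma). The list's camera adjusted p was 0.0634 without dTLec systemic replicate 2. That of the list of rapid stress transcription factors was 0.182 with all arrays and 0.0117 without dTLec control replicate 1.

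The direct comparison of the 2 responses asked which genes responded differently in dTLec. Of the 152 probe sets that passed in dTLec, 141 also passed in the wild type, all 141 in the same direction. Of the shared calls 108 were increases and 33 decreases. The fold changes of the 2 responses come from different arrays, while their tests use 1 estimate of the spread from all 8, so the 2 lists of calls are not independent. Among the probe sets that passed in the wild type, 90.8% of the raised and 91.3% of the lowered ones had the same sign in dTLec, and the median log2 fold change was 0.77 in the wild type and 0.34 in dTLec for the raised ones, and −0.56 and −0.23 for the lowered ones. Medians over probe sets chosen by their wild-type response favour the wild type. Over the 3209 probe sets chosen by the mean response of both genotypes, which favours neither, the slope of the dTLec on the wild-type response was 0.604, and between 0.503 and 0.758 with any single array left out.

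**Figure D1:**
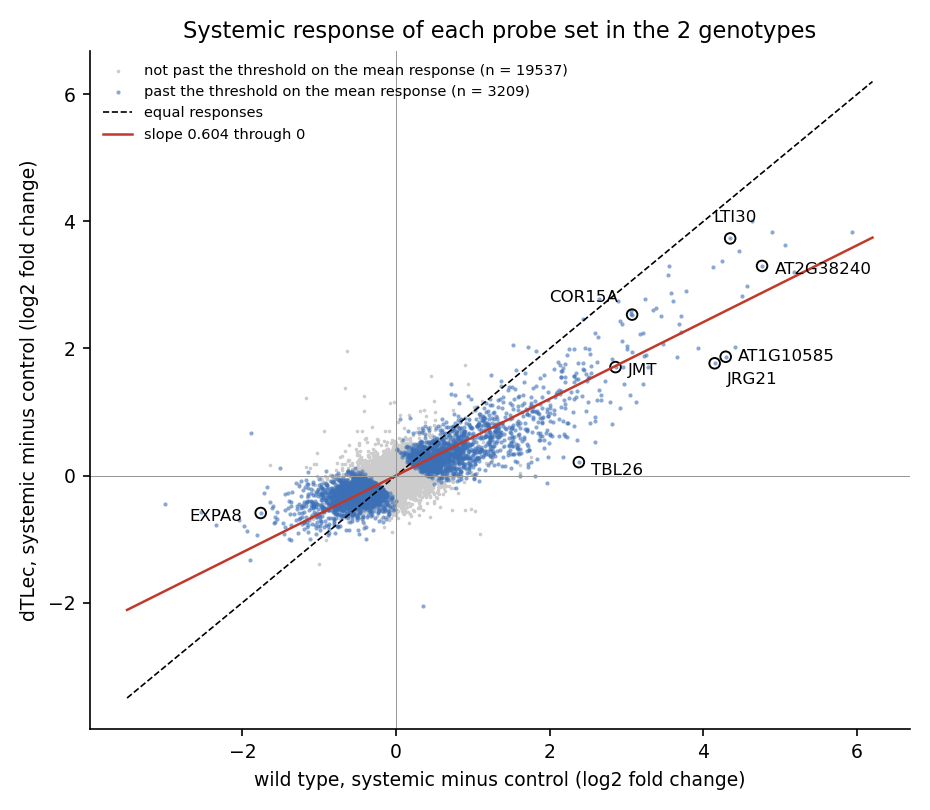
Log2 fold change between systemic and control leaves in the wild type (horizontal axis) and in dTLec (vertical axis), 1 point per probe set of 22746. Blue points are the 3209 probe sets past the threshold on the mean response, the dashed line marks equal responses, the red line has the slope of 0.604, and 8 named genes are circled. LTI30 (4.35 and 3.73) lies near the dashed line, and TBL26 (2.38 and 0.21) far under it.

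For single genes the difference of the responses passed the test at 1 probe set, to which the annotation used here gives no gene name. Its log2 fold change was −2.54 in the wild type and −0.57 in dTLec, a difference of 1.97 ± 0.12 (SE, n = 2 arrays per group, limma adjusted p 0.0187). With the replicate block 0 probe sets passed. At an unadjusted p under 0.05 there were 2553 probe sets in the main model. The 4 probe sets with the next smallest p did not pass. AT5G19110, an aspartyl protease gene, had responses of 2.59 and 0.53 (adjusted p of the difference 0.0515). The other 3, which have no gene name, had differences of −1.96, −1.53 and 2.56, with adjusted p of 0.0515, 0.0515 and 0.0683 (limma). The count of 1 became 5 without wild-type control replicate 1, 2 without wild-type control replicate 2, and 0 without dTLec control replicate 1, either wild-type systemic array or either dTLec systemic array. Without those arrays the adjusted p of the unnamed probe set lay between 0.0605 and 0.207. The jasmonate turnover list had a median difference of −1.20 (camera adjusted p 0.00306), and the adjusted p was 0.441 with an estimated correlation. The list of rapid stress transcription factors and kinases had a median difference of 0.53 (camera adjusted p 0.149), and its adjusted p was 0.00723 without dTLec control replicate 1, 0.0418 without wild-type control replicate 2, 0.00923 without wild-type systemic replicate 2 and 0.0443 without dTLec systemic replicate 1.

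**Figure D2:**
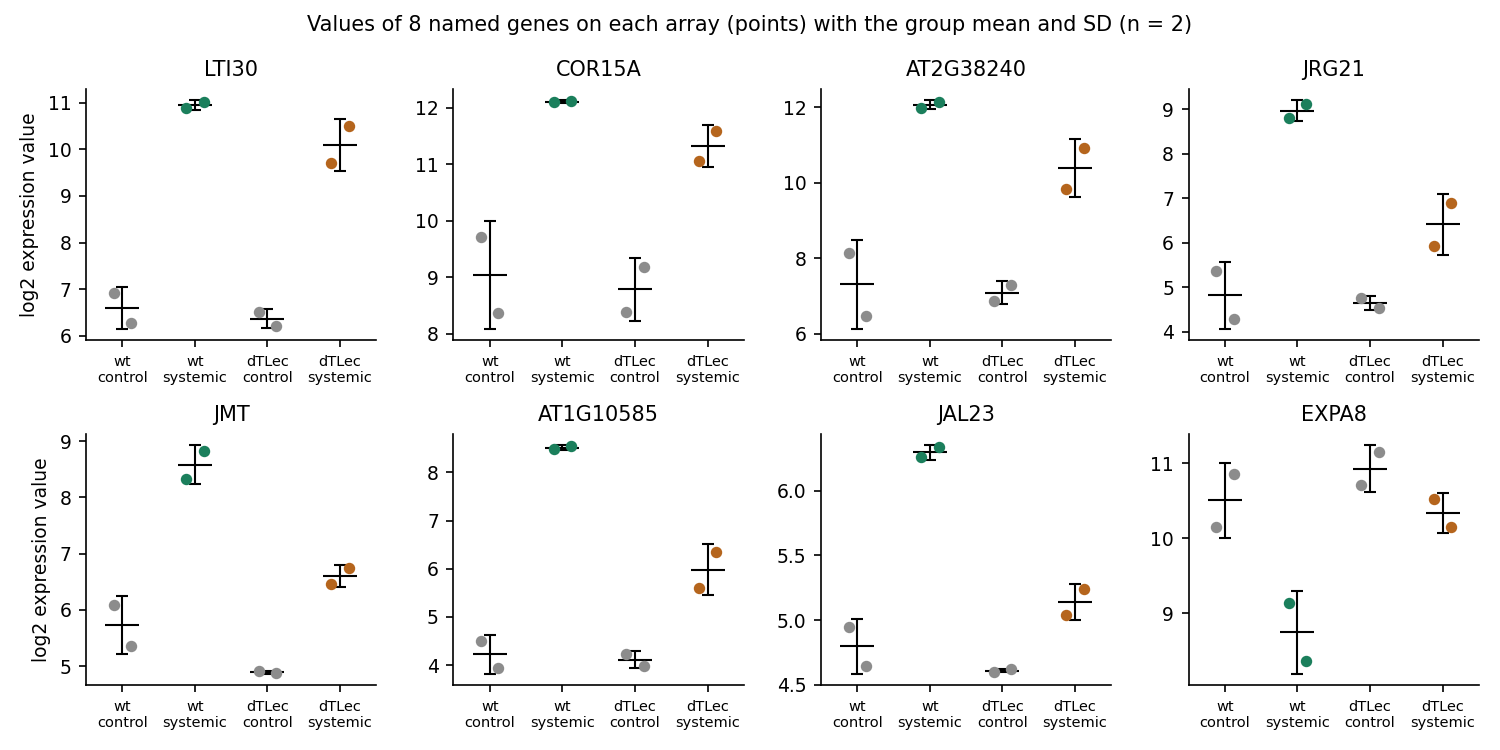
Log2 expression values (vertical axes, which do not start at 0) of 8 named genes in the 4 groups. Points are single arrays, horizontal bars the mean and error bars the SD of 2 arrays. JRG21 reached a mean of 8.97 in wild-type systemic leaves and 6.41 in dTLec systemic leaves, from 4.82 and 4.65 in control leaves.

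In control leaves the genotypes were compared to ask how dTLec differed without the systemic response, and no probe set passed (0 of 22746, limma, with 2104 at an unadjusted p under 0.05). The largest difference was at a probe set with no gene name in the annotation used here. Its mean was 7.83 ± 0.74 (SD, n = 2) in the wild type and 4.70 ± 0.21 in dTLec, a log2 difference of −3.13 with an adjusted p of 0.164 (limma). AT2G39920 (0.92) and 2 unnamed probe sets (0.89 and −0.78) had the same adjusted p, and another unnamed probe set (−1.14) had 0.169. GI, a circadian clock gene, differed by 1.00 ± 0.13 (SE, n = 2 arrays per group, limma adjusted p 0.173) and was the 1 clock gene measured by name. Leaving out wild-type control replicate 1 gave 2 probe sets past the threshold. One was the probe set with the largest difference, with −3.65 and an adjusted p of 0.0105. The fixed lists did not pass in this comparison with all arrays. Without wild-type control replicate 2 the jasmonate turnover list (median −0.89 in place of −0.20) and the list of rapid stress transcription factors and kinases had a camera adjusted p of 0.0331. The stress factor list had 0.0202 without dTLec control replicate 1, and the auxin list 0.0409 without wild-type control replicate 1.

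In systemic leaves the same comparison gave many differences. The 8 named genes lowest in dTLec relative to the wild type had all risen in the wild type. Both comparisons use the same 2 wild-type systemic arrays, so genes chosen as low in the first tend to be high in the second. JRG21 was 5.88-fold lower in dTLec, AT1G10585 5.80-fold and TBL26, a member of the trichome birefringence-like family, 4.49-fold. JMT, which methylates jasmonic acid, was 3.95-fold lower, with a log2 difference of −1.98 ± 0.25 (SE, n = 2 arrays per group). The genes of the transporters AT1G66760 and AT5G44050, both of the MATE family, were 4.17-fold and 3.81-fold lower, AT3G28270 4.11-fold and AT4G17470 4.02-fold. Higher in dTLec were EXPA8, 3.02-fold, and AT5G02540, a dehydrogenase-like gene, 2.72-fold. The plastid starch-degrading enzyme gene DPE1 was 2.26-fold higher, AT1G12845 2.57-fold, and AT3G62550, AT1G49200, AT1G67910 and AT5G47610 between 2.17-fold and 2.22-fold. The adjusted p of these 16 genes lay between 0.00448 and 0.0414 (limma). Some unnamed probe sets differed by more. The largest difference was at the same one as in control leaves, with means of 9.79 ± 0.14 (SD, n = 2) in the wild type and 4.59 ± 0.39 in dTLec. Its log2 difference was −5.20, with an adjusted p of 0.00448 and of 0.0541 without wild-type systemic replicate 2 (limma). Whether this probe set measures the gene disrupted by the insertion or another gene is not known here. Another unnamed probe set, one of those listed for the difference of the responses, was higher in dTLec by 3.26 ± 0.18 (SE, n = 2 arrays per group, limma adjusted p 0.00343) and had a log2 fold change of −3.01 in the wild type.

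The systemic leaves of the 2 genotypes differed at 1257 probe sets (limma), 513 higher and 744 lower in dTLec. At least 2-fold differences numbered 32 and 126. With the replicate block 213 probe sets passed, 63 higher and 150 lower. Both arrays of one genotype lay outside the range of the other at 54.7% of all probe sets, against 33.3% by chance. The count depended on single arrays. It was 3 without wild-type systemic replicate 2, 73 without wild-type systemic replicate 1, 46 without dTLec systemic replicate 1, 230 without dTLec systemic replicate 2 and 713 without either dTLec control array. Of the 16 named genes, 0, 8, 5, 13 and 15 passed in those 5 cases, and all kept their direction.

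The 4 jasmonate turnover genes measured by name, all JOX dioxygenase genes, were lower in dTLec systemic leaves, with a median log2 difference of −1.65. One of the 4, JRG21 (−2.56), passed over all probe sets, and all 4 passed when adjusted over the list alone. The camera adjusted p was 0.00102, and the adjusted p was 0.264 with an estimated correlation. JRG21 no longer passed without wild-type systemic replicate 1 (adjusted p 0.0739), wild-type systemic replicate 2 (0.15) or dTLec systemic replicate 1 (0.0907, limma), while AT2G38240 and AT5G05600 passed without either wild-type control array (0.0265 and 0.0335). OPCL1 (−1.01), UGT74B1 (−0.76) and COR15B (−0.77) were lower in dTLec, with adjusted p of 0.0231, 0.0341 and 0.0329 (limma). Without wild-type systemic replicate 2 these were 0.143, 0.179 and 0.183, and without wild-type systemic replicate 1, dTLec systemic replicate 1 or dTLec systemic replicate 2 none of the 3 passed. COR15B and UGT74B1 also did not pass without either dTLec control array (0.0545 and 0.0546). The auxin list was higher in dTLec, with a median of 0.62 and a camera adjusted p of 0.0432, and the adjusted p was 0.264 with an estimated correlation. In it IAA29 (0.62, adjusted p 0.0384) passed over all probe sets and 2 members over the list alone. Without wild-type systemic replicate 1 and dTLec systemic replicate 2 the list's adjusted p was 0.0921 and 0.109, and IAA29 passed when a wild-type control array was left out but not when any of the other 6 arrays was.

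Of 5 genes named as lectins, a group fixed before the data were examined, 2 passed in a comparison over all probe sets. JAL23, a jacalin-related lectin gene, went from a mean of 4.80 ± 0.21 (SD, n = 2) in control leaves to 6.30 ± 0.06 in systemic leaves of the wild type (limma adjusted p 0.00119). In dTLec it rose by 0.53 (limma adjusted p 0.102, and 0.0468 without either wild-type control array). Between the genotypes it differed by −1.16 in systemic leaves (adjusted p 0.00857). That difference had an adjusted p of 0.0501 without wild-type systemic replicate 1, 0.0833 without wild-type systemic replicate 2 and 0.062 without dTLec systemic replicate 1. JAL34 rose by 2.01 in the wild type (limma adjusted p 0.0341), which did not pass without wild-type control replicate 2 (0.0775), wild-type systemic replicate 2 (0.163) or either dTLec control array (0.054). EULS3 differed by −0.90 between the genotypes in systemic leaves (adjusted p 0.0763 over all probe sets, 0.0158 adjusted over the list alone), and by the same amount with an adjusted p of 0.0198 without either wild-type control array. Its wild-type response was 0.48 (adjusted p 0.273) and 0.83 (0.0309) without wild-type control replicate 1. JAL22 and JAL33 did not pass in any of these comparisons.

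Averaged over both genotypes, systemic leaves differed from control leaves at 3209 probe sets (limma), 1479 higher and 1730 lower. With the replicate block 1863 passed, 999 higher and 864 lower. After cyclic loess 1784 were higher and 1297 lower, and more were higher than lower without either wild-type systemic array, either dTLec control array or dTLec systemic replicate 2. LTI30 rose by 4.04 ± 0.20 (log2, SE, n = 4 arrays per leaf type), AT1G15010 by 4.19 and AT2G38240 by 4.03, and SCPL34, a carboxypeptidase-like gene, fell by 1.13. The count was 1576 without wild-type systemic replicate 2, 1617 without dTLec control replicate 2, 1756 without dTLec systemic replicate 2 and 2029 without wild-type systemic replicate 1. Averaged over both leaf types, dTLec differed from the wild type at 885 probe sets (limma), 350 higher and 535 lower, and at 103 with the replicate block. On simulated data this comparison made 21 false calls beside 200 changed probe sets in 1 simulation. AT5G02540 was higher by 1.08, TMT1, a vacuolar sugar transporter gene, by 0.69, and AT5G47610 by 0.79. In the other direction AT3G28270 had a log2 difference of −1.41, QQS, a gene linked to starch content, −0.99, MT1C, a metallothionein gene, −0.89, and GLC −0.83. The clock gene GI was higher by 0.67 (limma adjusted p 0.0202), which did not pass without wild-type systemic replicate 1 (0.0578), wild-type systemic replicate 2 (0.0855), dTLec control replicate 2 (0.0856) or dTLec systemic replicate 1 (0.0659). That count was 4 without wild-type systemic replicate 2, 5 without dTLec control replicate 2, 68 without dTLec systemic replicate 1, 82 without wild-type systemic replicate 1, 309 without dTLec control replicate 1 and 383 without dTLec systemic replicate 2.

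Markers of other leaf cell types and the array's own RNA controls were read beside these results. The guard-cell gene FAMA (wild type 0.41, dTLec −0.06), the phloem gene SWEET11 (0.08 and −0.13) and the cell-division gene AUR1 (0.07 and −0.11) did not pass in the systemic response of either genotype (log2 fold changes, limma). The log2 difference between the 3′ and 5′ probe sets of ubiquitin was 0.27 to 0.357 on the systemic arrays and 0.437 to 0.636 on the control arrays, 4 arrays each. Its exact two-sided permutation p was 0.0286, and 0.171 after Benjamini-Hochberg adjustment over 6 such comparisons. For GAPDH it was 0.873 to 1.13 in dTLec and 0.621 to 0.888 in the wild type (exact p 0.0571, adjusted 0.171), and for actin the exact p was 0.257 between genotypes and 0.629 between leaf types.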

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

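The tests of the signal range, of responsive probe sets chosen by size and of splits within leaf types were chosen after the results were seen.

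The response to wounding was smaller in dTLec than in the wild type across the responsive probe sets, with a slope of 0.604. If choosing probe sets by the wild-type response alone were the cause, the slope would be near 1 over probe sets chosen by the mean response. That mean weighs both genotypes equally, but the slope stayed at or under 0.758 with each single array left out. The value of 0.758 was that without the weaker of the dTLec systemic arrays, so this array adds to the smaller response. Neither that choice nor 1 weak array accounts for all of the smaller response. Whether the dTLec systemic arrays had a narrower signal range is not decided. The ratio of their spread to that of the wild-type systemic arrays was 0.981. Normalization gave all arrays nearly the same distribution, so this ratio would be near 1 in either case. Chance variation between arrays stays open: in limma's fry test of the difference of responses the larger p of the raised and lowered sets was 0.0372 when the sets were chosen by the test, which favours a small spread, and 0.0664 when chosen by size alone. A weaker systemic response of the mutant remains a hypothesis, and plants or leaves harvested at another stage of the response may give the same values, which 1 clock gene measured by name (GI) cannot decide.

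The jasmonate-oxidising dioxygenase genes JRG21, AT2G38240 and AT5G05600 kept a smaller share of their wild-type response in dTLec (ratios 0.426, 0.693 and 0.73) than the cold-regulated genes LTI30, COR15A and COR47 (0.859, 0.825 and 0.883), while the cold-regulated COR15B kept 0.399. This would be of interest if the mutant lost one branch of the response more than another. Of these ratios, 0 of 7 lay outside the middle 95% of raised probe sets with a similar wild-type response. Those ranges are wide (0.247 to 0.922 for JRG21 and 0.123 to 0.949 for COR15A) and would hold most ratios. AT2G38240 and AT5G05600 lay above the medians of those probe sets (0.651 and 0.578), and JRG21 below (0.639). LTI30, COR15A and COR47 lay above theirs (0.639, 0.548 and 0.525), and COR15B below (0.497). JOX1, with log2 fold changes of 0.55 in the wild type and 0.08 in dTLec, was not among the 7. Whether 1 uniform reduction of the whole response gives these ratios stays open.

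The median difference of the response, dTLec minus wild type, was −1.20 on the log2 scale for the jasmonate turnover list and −0.17 for 69 plastid-encoded genes. The camera adjusted p was 0.00306 and 0.0188, and the adjusted p was 0.441 and 0.896 with an estimated correlation. The single probe set whose responses differed past the threshold, which has no gene name, had a difference of 1.97 (limma adjusted p 0.0187). It did not pass with the replicate block.

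In 6 of the 109 probe sets that the rule for named genes, the lists or the lectin group picked, every array moved one way in the wild type and the other way in dTLec, and limma's test of the difference did not pass in any of them over all probe sets. The differences, dTLec minus wild type on the log2 scale, were −0.91 for AT2G39920, −0.89 for AT3G44450, −0.79 for AT1G76240, −0.59 for GLC, 0.65 for IAA29 and 0.19 for GSTU25. Over all probe sets 5.6% moved in this way, and chance gives 5.56%.

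Other splits of the 8 arrays were counted for the comparisons of 4 arrays against 4. For systemic against control leaves, 1 of 35 splits, the real one, gave as many calls in a fit of 2 groups. It gave 1738, against at most 96 in the others. Every other split mixes the leaf types within its groups, which can widen the spread and lower its count. A share of 1 of 35 is the smallest these splits can give, so they cannot exclude chance in the grouping of these 8 arrays. If the replicates are not separate plants, the splits do not cover chance between plants. For dTLec against the wild type the same fit without leaf type called 0 probe sets, against 885 in the fit of 4 groups (5082 at an unadjusted p under 0.05). All 35 of 35 splits necessarily gave as many as 0, so this count decides nothing about chance. The highest other count there was 1738, from the split by leaf type, which points to that structure of the samples. With leaf type as a term, 1 of 18 splits, the real one, gave as many as its 288 calls, the highest other gave 33, and 18 splits are too few for a share under 0.05.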

How the results depend on the processing

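The settings tried for the slope, the crossed pairing and the blocks within 2 groups were chosen after seeing the data, and the other settings before. Leaving out single arrays for the slope was set before its value was seen. No result turned its direction past the threshold in any setting. In the wild type, dTLec, control leaves and systemic leaves, and for both mean effects, the counts stayed within 1.5 times under centring, cyclic loess, the filter on dim probe sets, leaving out probe sets of several genes and the trended robust prior, and the first 2 moved the median fold change by at most 0.031. The balance of directions did change. In the wild type, where fewer were higher than lower, more were higher with centring (1418 and 1170), cyclic loess (1563 and 1053), the trended prior (1311 and 1230), no moderation (381 and 360), only its 2 groups (1038 and 940) and the replicate block (891 and 705). For leaf type, averaged over genotypes, this held with cyclic loess (1784 and 1297), no moderation (581 and 553) and the replicate block (999 and 864). Without moderation dTLec had 18 higher and 27 lower. The cause was not tested. Without moderation the counts fell to 741 (wild type), 45 (dTLec), 253 (systemic leaves), 1134 (leaf type, averaged over genotypes) and 127 (genotype, averaged over leaf types), with 3 for control leaves and 24 for the difference of responses. That difference also gave 8 calls with centring, 5 with the filter, 4 without probe sets of several genes and 10 with the trended prior. In dTLec the fit of its own 2 groups gave 324. At 2-fold or more, 619, 70, 158, 362 and 38 remained, which fewer genes can reach by construction. Of the 16 named genes of each comparison, 6 in the wild type, 0 in dTLec and 2 in systemic leaves passed without moderation. With the replicate block these numbers were 16, 4 and 14.

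Same-numbered arrays deviated from their group means in opposite directions (r −0.132 to −0.579). At the named genes checked, the replicate 1 arrays of the 4 groups had the same mean as the replicate 2 arrays. For LTI30 the values were 6.92, 10.88, 6.508 and 9.704 against 6.283, 11.02, 6.219 and 10.49. Removing the difference between replicate numbers from each probe set forces such opposite deviations. They therefore do not show whether the numbers pair the arrays. With the replicate block the counts were 1596 for the wild type, 16 for dTLec, 0 for the difference, 213 for systemic leaves, 1863 for leaf type and 103 for genotype. In fits of 2 groups the counts without a block, with the replicate block and with the crossed pairing were 1978, 1115 and 3293 in the wild type, 324, 722 and 732 in dTLec, 1200, 1692 and 1947 in systemic leaves, and 0 each in control leaves.

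With single arrays left out, the ranges were 806 to 2582 (wild type), 0 to 390 (dTLec), 0 to 5 (difference), 0 to 2 (control leaves), 3 to 1567 (systemic leaves), 1576 to 3581 (leaf type), 4 to 779 (genotype) and 0.503 to 0.758 (slope). Those of the jasmonate turnover median were 3.31 to 4.28 in the wild type, 1.62 to 2.66 in dTLec and −2.20 to −1.10 between genotypes in systemic leaves. Some counts rose and others fell, and the cause was not tested. With an estimated correlation the list no longer passed at medians of 3.79, 2.14 and −1.65 (adjusted p 0.259, 0.235 and 0.264).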

Other observations

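The gene families described here were defined after the annotation had been seen. In wild-type systemic leaves, 8 of 47 measured UDP-glycosyltransferase genes (UGT) rose and 2 fell (limma, adjusted over all probe sets). UGT76E12 rose by 2.13, UGT84A3 by 1.99 and UGT76E11 by 1.87 on the log2 scale, and UGT85A4 fell by 0.78. In the trichome birefringence-like family (TBL), 4 of 22 rose and 0 fell, led by TBL26 (2.38), TBL37 (1.22) and TBL41 (1.01). Among genes whose symbols begin with CYP, 6 of 26 fell, the cytochrome P450 gene CYP71B23 by 1.44, and CYP71B26 rose by 1.01. Whether all 26 are cytochrome P450 genes was not checked. Of the carboxypeptidase-like genes (SCPL), 4 of 29 fell, SCPL34 by 1.45, and scpl48 rose by 1.06. The camera adjusted p of these 4 families lay between 0.160 and 0.548, and none passed. In fry, which tests whether the members move on balance one way, the TBL family had an adjusted p of 0.0281. The other 3 of these families had between 0.0761 and 0.0816. Families not described here also passed in fry, among them BHLH (0.0196, lower on balance), LCR (0.0381, higher) and CHR (0.0489, lower).

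In systemic leaves, 6 of 47 UGT genes and 3 of 22 TBL genes were lower in dTLec than in the wild type and 0 were higher. The log2 differences were −1.37 for UGT84A3, −0.92 for UGT71B1, −2.17 for TBL26 and −1.09 for TBL37. The camera adjusted p was 0.0629 for both families. In wild-type systemic leaves, 2 of 9 XTH genes rose (XTH18 by 1.54 and XTH32 by 1.22), XTH33 fell (−1.64) and 6 did not pass. Of 10 EXPA genes, EXPA16 rose by 1.23, EXPA8 fell (−1.76) and 8 did not pass. Neither family passed in camera (adjusted p 0.548 and 0.964). XTH18 was lower (−0.86) and EXPA8 higher (1.59) in dTLec than in wild-type systemic leaves (adjusted p 0.0363 and 0.0414, limma).

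Of the 152 probe sets past the threshold in dTLec, 11 did not pass in the wild type, and 5 of the 11 have 1 gene name. The 5 genes, named here after their values were seen, had log2 fold changes in dTLec and in the wild type of 0.90 and 0.18 for AT5G02540, −0.81 and −0.39 for AT5G57785, −0.65 and −0.18 for AT4G37020, −0.64 and −0.10 for AT4G18740, and −0.45 and 0.13 for AT3G18500. The difference of the responses did not pass in any of the 11.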
